A study of Homo sapiens with 12 samples.

How the data were processed

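RNA from 2 established human lymphoid cell lines, Jurkat and L540, was measured on 12 Affymetrix Human Gene arrays, with 3 control and 3 ixazomib-treated arrays per line. Treatment was 25 nM for 24 h, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and the series text states that the experiments were done in biological triplicate.

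The deposited values are linear probe set intensities, 1 per probe set and array. Per the series design text, the authors adjusted the background and quantile normalized the arrays with RMAExpress, and then applied limma at a false discovery rate of 0.05, which gave 764 genes in Jurkat and 5819 in L540. The version of RMAExpress and the step from its log2 scale to the linear intensity values are not given in the sources used here. The median of log2 intensity averaged 5.4 over the Jurkat arrays and 5.08 over the L540 arrays. The 10th to 90th percentiles differed between the lines by 0.199 to 0.421 on the log2 scale, against at most 0.0615 within Jurkat and 0.0897 within L540. The lines were therefore taken as normalized separately, and the planned test of L540 control against Jurkat control, with its gene lists, was not run. The number of arrays limits the precision, and p-values measure the spread between 3 cultures of 1 line.

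Probe sets were named through the platform annotation supplied with the values. Of 53617 probe sets, 16098 had 1 gene symbol, 0 had several and 37519 had none here. Affymetrix control probe sets could not be picked out, so all 53617 were tested. Of neighbouring named probe sets, 98.5% of 16097 pairs lay on the same chromosome. For 779 genes with several probe sets the one with the highest mean over the 12 arrays was used, giving 14884 genes.

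Intensities were converted to log2 and tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust prior, two-sided, Benjamini-Hochberg adjustment over all probe sets, threshold 0.05). Each line was tested on its own 6 arrays. The difference between the lines, L540 minus Jurkat, was tested as an interaction over all 12 arrays and 4 group means. The correlation of the lines' log2 fold changes across genes was described without a p-value.

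Gene lists were tested with limma's camera at gene level, with a preset inter-gene correlation of 0.01 and adjustment over 23 response lists. These were immunoproteasome and antigen processing, heat shock, the endoplasmic reticulum unfolded protein response, ATF4, NRF2, metallothioneins, autophagy and lysosome, MYC targets, the MYC network, the CHK1 and ATR checkpoint with homologous recombination, DNA replication, mitosis and G2/M, p53 targets, pro-apoptotic genes, anti-apoptotic genes, NF-kB targets, interferon response, AP-1 and immediate early genes, cholesterol synthesis, glycolysis and hypoxia, cytosolic ribosomal proteins, the respiratory chain and T cell signalling. The 20S core proteasome (1 of 19 genes measured), the 19S regulatory particle (2 of 22) and replication-dependent histones (0 of 26) had under 3 measured members and were not tested. Marker lists of T cells, Hodgkin cells, B cells, myeloid, epithelial, erythroid and NK cells were counted and tested in the same way, adjusted among themselves.

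The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took MYC and CHEK1, which the series title names, in every comparison. It added the 5 largest increases and 5 largest decreases per line and for the difference between lines, among genes past the threshold, in each line with the treated arrays all beyond the controls. Small RNAs, pseudogenes and uncharacterised loci were passed over in this part and the next gene was taken. It also took up to 2 members per response list and line with the largest absolute change past the threshold, or the largest 1 where none passed.

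Alternatives were a filter on dim probe sets (mean over the 12 arrays above 5.259 on the log2 scale), centring of arrays, a second quantile normalization, an intensity trend with a robust prior, array weights, only named probe sets, the replicate number as a block, all 12 arrays in 1 fit, omission of each array, an estimated inter-gene correlation, fry, ranks in camera and the mean of a gene's probe sets. Added after seeing the data were tests without the leading unplaced probe set IDs and on linear intensities.

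The procedure was tested on simulated data with 200 of 53617 probe sets changed. At log2 changes of 0.5, 1, 2 and 3, 4%, 60%, 86% and 100% were recovered with the Jurkat arrays, 14%, 60%, 100% and 100% with the L540 arrays and 10%, 58%, 86% and 92% for the difference, with 1 false call of 126, 7 of 144 and 8 of 131. A list raised by 0.5 was called in each comparison. In simulated data with no raised list, 0 of 23 lists were called. The simulated noise was drawn independently per probe set, so it cannot show how often lists of correlated genes are falsely called. In the real data 6470 probe sets passed in L540 and 3798 in the difference. With more changed probe sets the adjustment is less strict, so the recovery shares for these 2 comparisons may be too low for the real data.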

Results

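Gene expression was measured in 2 human lymphoid cell lines with and without ixazomib, an orally available inhibitor of the proteasome, the complex that degrades ubiquitin-tagged proteins. Jurkat is an established T-cell line, described in the labels as T-cell lymphoma, and L540 is an established Hodgkin lymphoma line. Treated cells had received 25 nM ixazomib for 24 h. Each line had 3 control and 3 treated arrays, which the series describes as biological triplicates, giving 12 arrays in 4 groups. The arrays held 53617 probe sets, of which 16098 could be named here, for 14884 genes. The number of arrays limits the precision of each value. The median intensity per array lay between 41.4 and 43.3 in Jurkat and between 32.8 and 34.6 in L540. Pearson's r between arrays of a group, across probe sets on the log2 scale, was 0.9911 to 0.9926 in the Jurkat groups and 0.992 to 0.9925 in the L540 controls. It was 0.9871 to 0.9908 in ixazomib-treated L540, where replicate 3 stood slightly apart. From the distribution of their values, the 2 lines were taken as normalized separately, so a control line was not tested against the other. Side by side, and with that limit, the T-cell kinase LCK had a mean log2 intensity of 11.12 in Jurkat control and 5.27 in L540 control, and IRF4, a lymphoid transcription factor gene, had 4.66 and 11.76. LCK and IRF4 were chosen after their values were seen.

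The first question was how L540 responded to ixazomib. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose most, by 3.80 ± 0.097 on the log2 scale (SE, 3 against 3 arrays, adjusted p = 7.89e-05). Of the 15 measured genes of the heat shock list, 13 rose, among them the co-chaperone gene BAG3 (log2 fold change 2.67 ± 0.105) and the chaperone gene HSPA1A (2.43 ± 0.0779). HSPA1A and its neighbour HSPA1B are near-identical copies, so their values are uncertain to tell apart. Of the 21 measured genes of the ATF4 integrated stress response, 13 rose and none fell, including DDIT3, which encodes the stress transcription factor CHOP (2.37 ± 0.143), and SESN2 (1.64 ± 0.0813). The ATF4 list rose against the other genes (camera adjusted p = 6.53e-08, 0.14 with an estimated correlation), as did the heat shock list (adjusted p = 2.09e-11, 0.103 with an estimated correlation). In the list of endoplasmic reticulum unfolded protein response genes, 5 of 14 rose, led by ERN1 (1.34 ± 0.116) and HYOU1 (0.51 ± 0.0711), and the list did not pass (adjusted p = 0.0594), with 5 higher and 1 lower adjusted over the list alone.

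In the autophagy and lysosome list 11 of 25 rose and none fell, with GABARAPL1, an autophagosome protein gene, at 2.26 ± 0.123 and the cargo receptor gene SQSTM1 at 1.32 ± 0.0737 (list adjusted p = 6.72e-06, 0.14 with an estimated correlation). The NRF2 oxidative stress list had 5 of 14 genes higher and 1 lower, the same numbers adjusted over the list alone, and passed (adjusted p = 0.0273, 0.271 with an estimated correlation). Few genes of the proteasome itself were named on the array, and no list of them was tested. Of those that were named, the assembly factor POMP rose by 0.53 ± 0.0735, the ubiquitin receptor ADRM1 by 0.90 ± 0.0914 and SEM1 by 0.43 ± 0.104. Of the AP-1 and immediate early genes, 7 of 17 rose, led by DUSP1 (1.37 ± 0.0957) and IER5 (1.25 ± 0.084), with 8 higher and 1 lower adjusted over the list alone, and the list passed (adjusted p = 0.00243, 0.266 with an estimated correlation). STYK1, a kinase-like gene, and MIR22HG, a noncoding RNA gene, were also among the 5 largest increases with small RNA genes passed over, at 3.00 ± 0.119 and 2.70 ± 0.0879. The microRNA gene MIR616, passed over by that rule, rose by 3.06. The STYK1 mean in L540 control was 4.72, below the median of all probe set means (5.26), and without detection calls the size of such a fold is uncertain.

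The series title names MYC and CHK1, the product of CHEK1, and both transcripts fell in L540. MYC, a transcription factor gene that drives growth, went from a mean log2 intensity of 10.0 ± 0.0309 (SD, n = 3) in controls to 8.61 ± 0.0705 with ixazomib, a fold change of -1.39 ± 0.077 on the log2 scale (limma adjusted p = 0.000385). CHEK1, a checkpoint kinase gene, fell by 1.10 ± 0.0762 (adjusted p = 0.000597). Of the 33 MYC targets measured, 17 fell and 2 rose, with the lowest values in HK2, a glycolytic enzyme gene (-1.87 ± 0.101), and UNG, a DNA repair gene (-1.54 ± 0.0809). The 2 that rose were the chaperonin gene HSPD1 (0.57) and the ribosome biogenesis gene WDR74 (0.31), named after their values were seen. The WDR74 call was lost without any 1 of the 6 arrays (adjusted p = 0.0894 to 0.17) and after centring (0.0717). The list fell against other genes (adjusted p = 2.81e-09, 0.14 with an estimated correlation). In the network of MYC partners and antagonists, 3 of 10 rose and 3 fell, with MXD1, a MYC antagonist gene, higher by 1.55 ± 0.08, and the list did not pass (adjusted p = 0.568).

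In the mitosis and G2/M list of L540, 40 of 41 fell, with a median of -1.01, among them CDK1, the mitotic kinase gene (-1.67 ± 0.0777), and KIF20A, a mitotic kinesin gene (-1.49 ± 0.091). In the DNA replication list 22 of 25 fell, with a median of -1.05, led by the replication factor gene GINS2 (-1.76 ± 0.16) and by UHRF1, a DNA methylation maintenance gene (-1.72 ± 0.0907). Of the checkpoint and homologous recombination genes, 15 of 28 fell and none rose, including the nuclease gene EXO1 (-1.54 ± 0.1). Adjusted p was 3.04e-29 for mitosis, 5.95e-19 for replication and 2.81e-09 for the checkpoint list, and 0.12, 0.103 and 0.249 with an estimated correlation. The 5 largest falls were CDCA7 (-2.47 ± 0.0867), CD160 (-2.46 ± 0.0842), ALOX5AP, which is needed for leukotriene synthesis (-2.36 ± 0.0905), the surface enzyme gene CD38 (-2.13 ± 0.134) and the transcription factor gene MYB (-2.08 ± 0.079).

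Cholesterol synthesis genes had 8 of 16 lower and 1 higher, with INSIG1 at -1.14 ± 0.0784 and ACAT2 at -0.70 ± 0.106 (adjusted p = 0.00275, 0.243 with an estimated correlation). Glycolysis and hypoxia genes had 5 of 14 lower, HK2 and PGAM1 most (adjusted p = 0.0274, 0.266 with an estimated correlation). Respiratory chain genes had 2 of 10 lower, COX7B (-0.71 ± 0.0747) and COX5A (-0.42 ± 0.0767), with an adjusted p of 0.0151, and 0.266 with an estimated correlation. Of 31 cytosolic ribosomal protein genes 2 fell, RPS23 and RPS24, and the list passed (adjusted p = 0.000453, 0.318 with an estimated correlation). The p53 targets (4 of 14 higher, 1 lower), the pro-apoptotic genes (2 of 11 higher, 1 lower) and the NF-kB targets (6 of 22 higher, 2 lower) did not pass as lists, with adjusted p of 0.327, 0.74 and 0.191. Among their members PMAIP1, a pro-apoptotic BCL2 family gene, rose by 0.99 ± 0.0783, TIGAR by 0.87 ± 0.0842, BAK1 by 0.51 ± 0.0935, IRF1 by 0.85 ± 0.12 and ICAM1 by 0.76 ± 0.0717. The interferon list did not pass (adjusted p = 0.409) and held opposite changes, IFI44 at 1.73 ± 0.146 and IFI44L at -1.15 ± 0.188. IFI44L was left out by the filter on dim probe sets, which takes the mean over both lines, so the size of its fall may be uncertain. Metallothioneins MT2A (-0.97 ± 0.142) and MT1X (-0.38 ± 0.09) fell and 6 of 8 did not pass (list adjusted p = 0.21). The T cell signalling genes LAT (-0.68 ± 0.0867) and CXCR4 (-0.32 ± 0.0749) fell and 15 of 17 did not pass (adjusted p = 0.0946). The antigen processing gene ERAP1 fell by 0.55 ± 0.0737 and 3 of 4 did not pass (adjusted p = 0.453), and of 9 anti-apoptotic genes none passed, 0 also when adjusted over the list alone (list adjusted p = 0.76).

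Adjusted over the list alone in L540, 14 heat shock genes rose and 1 fell, 14 ATF4 genes rose and 1 fell, and 13 autophagy genes rose. On the same count 40 mitosis, 24 replication and 18 checkpoint genes fell, 23 MYC targets fell and 3 rose, and the MYC network again had 3 higher and 3 lower. Cholesterol synthesis had 9 lower and 2 higher, glycolysis 5 lower, the respiratory chain 3 lower, ribosomal proteins 2 lower, metallothioneins 2 lower, T cell signalling 2 lower, and antigen processing 2 lower and 1 higher. NF-kB targets had 8 higher and 4 lower, interferon genes 5 and 3, p53 targets 4 and 1, and pro-apoptotic genes 3 and 2. The medians of the p53 (-0.022), pro-apoptotic (-0.0537) and anti-apoptotic lists (-0.0117) were negative while their means (0.133, 0.0517 and 0.035) and the direction of the test were positive. Over all 53617 probe sets, 6470 passed adjusted p 0.05 in L540, 3462 higher and 3008 lower, and 897 of them changed at least 2-fold. The submitters state 5819 significant genes at the same threshold, a count of genes and not of probe sets. Of the 14884 genes named here, 2778 passed. The submitters' filter and gene summary are not given in the sources used here, so the counts are not directly comparable. Leaving out L540 control replicate 1, 2 or 3 gave 3625, 3586 or 3655 probe sets, and with only named probe sets tested 4216 passed. The calls of COX5A, CXCR4, MT1X, RPS24 and SEM1 were lost without most single arrays (COX5A without all but ixazomib replicate 3, SEM1 without all but control replicate 3, the other 3 without any of the 6) and BAK1 without control replicate 1 or 2, and centring the arrays ended CXCR4, MT1X and RPS24.

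In Jurkat, the second comparison, ixazomib gave fewer calls and nearly all were increases. IFI44, an interferon-inducible gene, rose by 3.30 ± 0.123 on the log2 scale (limma adjusted p = 0.000919). CFAP47, a cilia-associated gene, rose by 2.64 ± 0.121 and CLU, which encodes the extracellular chaperone clusterin, by 2.64 ± 0.0795. The control means of IFI44 (4.98) and CLU (5.03) lay below the median of all probe set means (5.26) and that of CFAP47 (5.27) close to it, so the size of these folds is uncertain. ABHD4, a lipid hydrolase gene, rose by 1.71 ± 0.143 and CD68, a lysosomal membrane protein gene best known from macrophages, by 1.71 ± 0.12. Only 3 named genes fell, namely IGLL1 (-0.94 ± 0.0924), the lysosomal protease gene CTSH (-0.62 ± 0.081) and DSCC1, a replication factor gene (-0.58 ± 0.0733).

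The NRF2 oxidative stress list rose in Jurkat. Of its 14 genes, 3 passed over all probe sets and 12 adjusted over the list alone, and all of these were higher. They included SRXN1, an antioxidant enzyme gene (0.86 ± 0.101), and the NRF2 partner gene MAFG (0.69 ± 0.0875), and the third was the glutathione reductase gene GSR (0.66), chosen after its value was seen and lost without any 1 of the 6 arrays (adjusted p = 0.094 to 0.146). HMOX1 had a value of -0.14 (adjusted p = 0.698). The list's adjusted p was 5.45e-12, and 0.0436 with an estimated correlation. In the autophagy and lysosome list 3 of 25 rose, and 6 adjusted over the list alone, with GABARAPL1 at 1.28 ± 0.12, the lysosomal protease gene CTSD at 1.01 ± 0.0844 and VCP at 0.53 (list adjusted p = 2.28e-06, 0.108 with an estimated correlation). The VCP call was lost without any 1 array (adjusted p = 0.156 to 0.243) and after centring (0.0746). Of 21 ATF4 genes 2 rose, ASNS, for asparagine synthesis (0.63 ± 0.0766), and CTH (0.58 ± 0.0756), with 4 higher adjusted over the list alone (adjusted p = 0.000969, 0.207 with an estimated correlation). ADRM1 rose by 0.63 ± 0.0788, IL7R by 0.83 ± 0.101, and IFI44 was the only 1 of 20 interferon genes past the threshold. Adjusted over the list alone 3 interferon genes rose and 1 fell, and the list passed (adjusted p = 0.00759, 0.154 with an estimated correlation). Metallothioneins had none of 8 past and 1 higher adjusted over the list alone (adjusted p = 0.0222, 0.174 with an estimated correlation).

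MYC in Jurkat went from 10.64 ± 0.0424 (SD, n = 3) to 10.50 ± 0.0665, a log2 fold change of -0.14 with a 95% interval from -0.325 to 0.0431 (adjusted p = 0.627). CHEK1 had a log2 fold change of -0.21 with an interval from -0.385 to -0.0375 (adjusted p = 0.422). None of 41 mitosis genes passed over all probe sets, but 31 fell adjusted over the list alone, with a median of -0.29, and the list fell (adjusted p = 1.41e-23, 0.0436 with an estimated correlation). The checkpoint list (0 of 28, 11 lower adjusted over the list alone, adjusted p = 2.97e-10), the replication list (0 of 25, 6 lower, adjusted p = 1.2e-10) and MYC targets (0 of 33, 0, adjusted p = 4.68e-07) also moved down as lists, with 0.15, 0.154 and 0.154 as adjusted p with an estimated correlation. The heat shock list had none of 15 past, a median of -0.12 and a downward call (adjusted p = 0.000472, 0.178 with an estimated correlation). The unfolded protein response list also had a downward call, with 0 of 14 past and 2 lower adjusted over the list alone (adjusted p = 0.000969, 0.108 with an estimated correlation). Cholesterol synthesis (0 of 16) and ribosomal protein genes (0 of 31) were called downward with adjusted p of 0.000441 and 0.000276, and 0.178 and 0.104 with an estimated correlation. The largest value in the unfolded protein response list was that of XBP1, its transcription factor gene (-0.53, adjusted p = 0.0726), and in the checkpoint list that of EXO1 (-0.44, adjusted p = 0.0828). The other 10 lists did not pass in Jurkat, with adjusted p from 0.289 to 0.973, and adjusted over the list alone only T cell signalling had any, 1 higher and 3 lower. The pro-apoptotic list had a median of 0.0346 and a mean of -0.0163, and the NF-kB list a median of 0.0111 and a mean of 0.0144 with a downward direction in the test.

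Over all 53617 probe sets, 201 passed in Jurkat, 190 higher and 11 lower, and 77 changed at least 2-fold. At an unadjusted p under 0.05 there were 5206. The submitters state 764 significant genes, and of the 14884 genes named here 78 passed, with the same limit on comparing these counts. Leaving out any 1 of the 6 arrays (control replicate 1, 2 or 3, or ixazomib replicate 1, 2 or 3) gave 38 to 52 probe sets, and IGLL1, CTSH, DSCC1, ADRM1, ASNS, CTH, SRXN1, MAFG and IL7R were lost without any 1 of them, whereas IFI44, CFAP47, CLU and CD68 passed without each in turn. GABARAPL1 was lost without any control or ixazomib replicate 1, CTSD without all but ixazomib replicate 1, ABHD4 without control replicate 1 or ixazomib replicate 2 or 3, CTH and MAFG after centring, and DSCC1 after a second quantile normalization. Of the 201, 94.5% were higher, against 74.6% of 512 with an intensity trend and robust variance prior, 78% of 409 without dim probe sets, 73.4% of 237 among named probe sets, 82.5% of 480 with all 12 arrays in 1 fit and 60.7% of 494 on linear intensities, an alternative chosen after seeing the data.

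**Figure D1:**
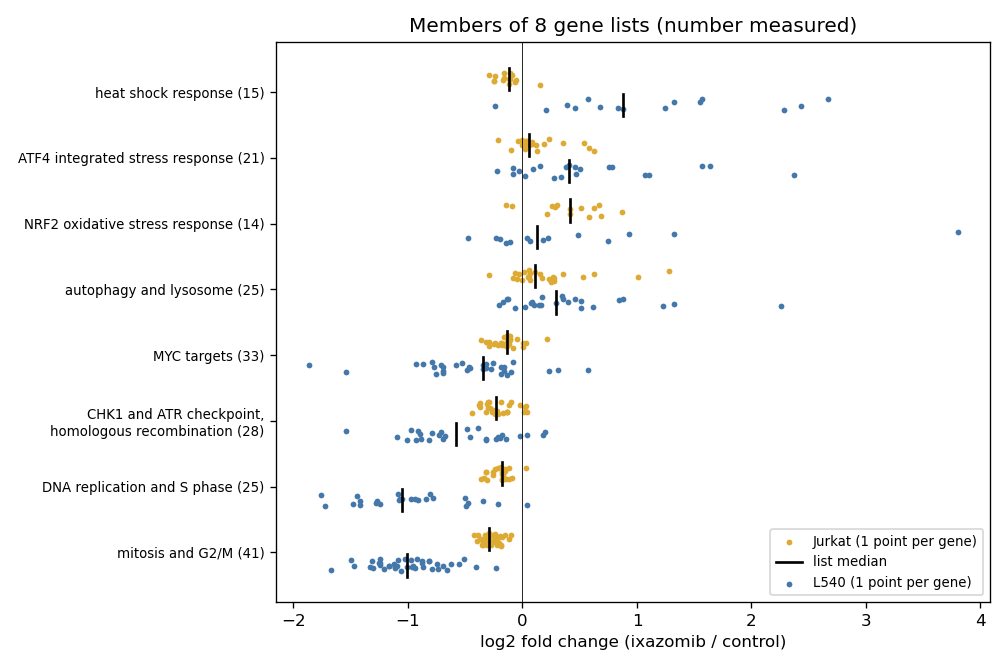
Log2 fold change of each measured member of 8 gene lists, with 1 point per gene, Jurkat in yellow and L540 in blue, and the list median as a black bar (position within a row is random). In L540 the medians of the mitosis and replication lists lie at -1.01 and -1.05, and in Jurkat at -0.292 and -0.18.

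Differences between the lines were tested with the interaction of line and treatment over all 12 arrays. HMOX1 differed by 3.94 ± 0.132 (L540 minus Jurkat, adjusted p = 1.76e-07), HSPA1A by 2.55 ± 0.0978, BAG3 by 2.51 ± 0.146 and DDIT3 by 2.33 ± 0.182. HSPA1B, uncertain to tell apart from HSPA1A, differed by 2.40 ± 0.0944. The most negative differences were those of ALOX5AP (-2.78 ± 0.109), CD160 (-2.53 ± 0.222), CDCA7 (-2.38 ± 0.136), SMIM10 (-2.01 ± 0.141) and MYB (-1.91 ± 0.11). In Jurkat control CD160 (4.79) and SMIM10 (5.06) were below the median of all probe set means. Without detection calls, the size of their differences is uncertain. MYC differed by -1.25 ± 0.0986 (adjusted p = 4.92e-05), and CHEK1 by -0.89 ± 0.0937 (adjusted p = 0.000292). The difference passed for 13 of 15 heat shock genes (median 1.08), 35 of 41 mitosis genes (median -0.74), 19 of 25 replication genes (median -0.817) and 8 of 21 ATF4 genes in the positive direction, with 1 ATF4 gene, ASNS, negative at -0.47. Adjusted p for those lists was 3.04e-18, 1.07e-29, 1.45e-20 and 1.33e-05, and 0.00826, 0.021, 0.021 and 0.109 with an estimated correlation. The unfolded protein response list also differed, with 6 of 14 genes past (adjusted p = 0.000192, 0.043 with an estimated correlation). Adjusted over the list alone the positive counts were 14 for heat shock, 12 for ATF4, with 2 negative, and 7 for the unfolded protein response, with 1 negative. The negative counts were 39 for mitosis and 21 for replication. MYC targets (12 of 33 negative, 1 positive, 16 and 1 adjusted over the list alone) and the checkpoint list (11 of 28 negative, 14 and 1 positive) differed too, with adjusted p of 1.21e-05 and 9.91e-06, and 0.114 and 0.233 with an estimated correlation. The NRF2 list did not pass (adjusted p = 0.19), with 2 genes more positive in L540 and 4 more negative, a median of -0.206 and a mean of 0.0747. Of 53617 probe sets 3798 passed, 1849 more positive and 1949 more negative in L540. Each disease is represented by 1 line, so line and disease cannot be separated.

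**Figure D2:**
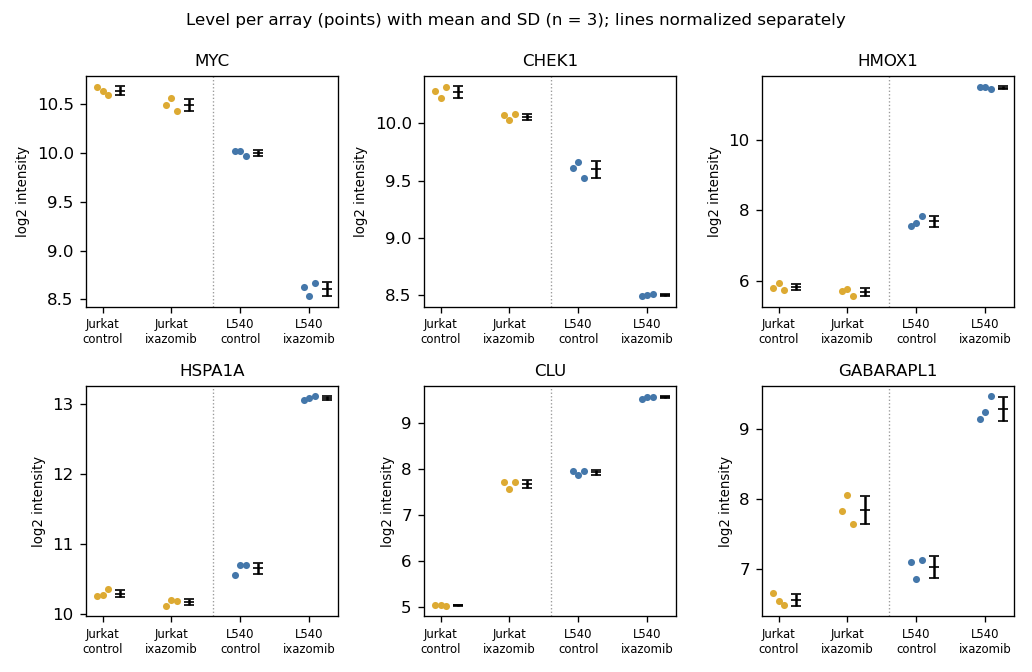
Log2 intensity of 6 genes on each of the 12 arrays (points) with mean and SD (bars, n = 3 per group); the dotted line separates Jurkat from L540, whose values were taken as normalized separately. MYC averages 10.0 in L540 control and 8.608 with ixazomib.

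Across the 14884 genes, the log2 fold changes of the lines had a Pearson r of 0.304 and a Spearman rho of 0.245. This is a description across genes, which are not independent replicates, and the lines shared no control arrays. Of the 75 genes higher in Jurkat, 36 were also higher in L540, against 6.858 for independent lists. CLU, CFAP47, ABHD4, IFI44 and GABARAPL1 were among these 36, with L540 values of 1.64, 1.64, 2.22, 1.73 and 2.26. Genes called lower in both numbered 1, DSCC1, against 0.285, and 2 genes, EMP3 and PFN2, had opposite signs. DSCC1, EMP3 and PFN2 are named after their values were seen. The EMP3 and PFN2 calls were lost without any 1 array in Jurkat (adjusted p = 0.134 to 0.242), and in L540 without any 1 except, for PFN2, ixazomib replicate 3 (0.0589 to 0.123). Centring ended PFN2 in Jurkat (0.0556) and EMP3 in L540 (0.0528). Of the Jurkat calls, 39 did not pass in L540.

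**Figure D3:**
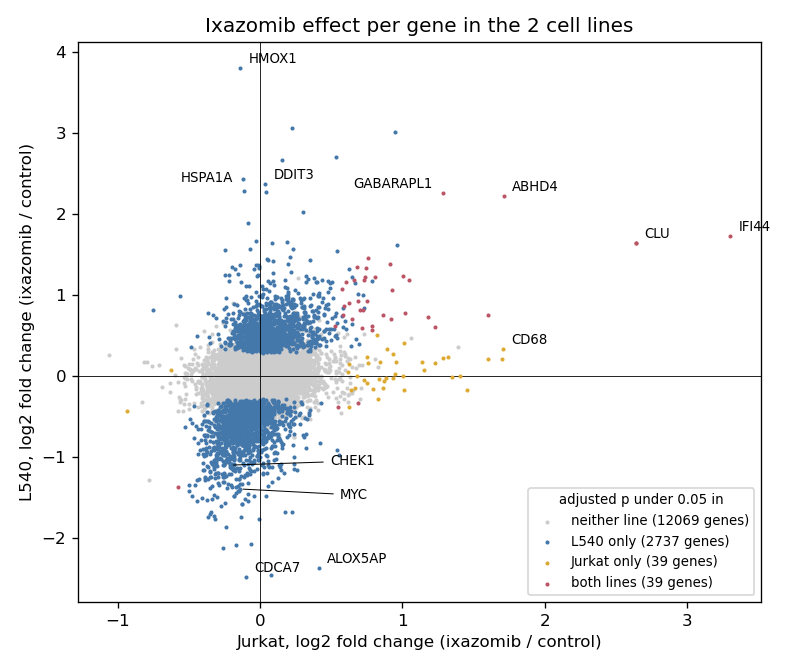
Log2 fold change in L540 (vertical axis) against Jurkat (horizontal axis), 1 point per gene, coloured by the lines in which adjusted p was under 0.05. Most of the 14884 genes cluster near 0 in Jurkat, and the 39 genes called in both lines lie mainly in the upper right.

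Markers of other cell types were counted in the same fits, and genes named here were chosen after their values were seen. In L540, 4 of 17 T cell markers fell (CD2 most, at -1.33), 3 of 8 NK and cytotoxic markers fell (FGFBP2, PRF1 and NKG7, the last lost without control replicate 1 or 3 or ixazomib replicate 1, adjusted p = 0.0548 to 0.0605), and 6 of 17 Hodgkin cell markers fell and 2 rose. PDCD1LG2, encoding the PD-1 ligand PD-L2, fell by 1.45, and CD80, a co-stimulatory ligand gene, rose by 1.03. FGFBP2 and CD80 were left out by the filter on dim probe sets, which takes the mean over both lines, so the size of their changes may be uncertain. Of 14 B cell markers 1 fell, of 12 myeloid markers 1 fell, of 11 epithelial markers 1 rose and of 4 erythroid markers none passed. No marker list passed in L540 by camera, with the lowest adjusted p at 0.0773. With fry, a test of a different question, the T cell, Hodgkin cell and NK lists (adjusted p = 0.000799 each) and the myeloid list (0.0405) passed. In Jurkat CD68 was the only 1 of the 12 myeloid markers to pass, and no marker of the other 6 lists did. No marker list passed in Jurkat by camera (lowest adjusted p at 0.106) or by fry (lowest at 0.0665).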

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

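Some tests below were chosen after the results were seen. They are those of spread and of a single array behind the number of calls, of the share of increases and of myeloid markers.

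The ixazomib effect differed between the lines, by the interaction test in limma, for 55 of the 78 genes named by the rule, with adjusted p from 1.76e-07 to 0.0443. The rule picked most of these genes by the size of their change in the same fits, and some by the difference itself. A high share was therefore built in, and over all 14884 named genes 1710 passed. Of the 55, 22 were positive on the log2 scale, L540 minus Jurkat. They were HMOX1 at 3.94, HSPA1A at 2.55, BAG3 at 2.51, HSPA1B at 2.40, DDIT3 at 2.33, MIR22HG at 2.17, STYK1 at 2.06, SESN2 at 1.56, ERN1 at 1.53 and DUSP1 at 1.38. The other positive ones were IER5 at 1.26, PMAIP1 at 1.09, IRF1 at 1.09, MXD1 at 1.00, GABARAPL1 at 0.97, TIGAR at 0.85, HYOU1 at 0.80, HSPH1 at 0.75, SQSTM1 at 0.70, CTSH at 0.70, XBP1 at 0.57 and ICAM1 at 0.53.

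The other 33 were negative. The most negative were ALOX5AP at -2.78, CD160 at -2.53, CDCA7 at -2.38, SMIM10 at -2.01, MYB at -1.91, CD38 at -1.87, HK2 at -1.63, IFI44 at -1.57, MT2A at -1.53, UNG at -1.46, GINS2 at -1.45, IFI44L at -1.42, UHRF1 at -1.40, CD68 at -1.38 and CDK1 at -1.33. Then came MYC at -1.25, KIF20A at -1.19, IL7R at -1.11, EXO1 at -1.10, INSIG1 at -1.06, CLU at -1.003, CFAP47 at -1.002, CDC6 at -0.91, CHEK1 at -0.89, LAT at -0.89, DSCC1 at -0.78, COX7B at -0.61, TP53INP1 at -0.59, PGAM1 at -0.55, NEK2 at -0.49, ASNS at -0.47, ACAT2 at -0.47 and JUND at -0.39.

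Of the 55, 7 lost the call when 1 array was left out, with adjusted p from 0.0503 to 0.11. ACAT2 and JUND lost it without any array except L540 ixazomib replicate 3, TP53INP1 without any except Jurkat control replicate 3, Jurkat ixazomib replicate 1 and L540 ixazomib replicate 2, and CFAP47 without any except L540 control replicate 2 and ixazomib replicate 3. CTSH lost it without Jurkat control replicate 2 or 3, Jurkat ixazomib replicate 2 or 3, or L540 ixazomib replicate 2. MXD1 lost it without Jurkat ixazomib replicate 1 or 3, L540 control replicate 2 or 3, or L540 ixazomib replicate 1. PGAM1 lost it without Jurkat control replicate 1 or 2, Jurkat ixazomib replicate 1 or 3, L540 control replicate 2 or 3, or L540 ixazomib replicate 2. Some differences rest on a dim control mean, below the median of all probe set means (5.26), and their size is uncertain. In Jurkat these were IFI44 (4.98), CLU (5.03), STYK1 (5.08), CD160 (4.79), SMIM10 (5.06) and IFI44L (3.96), and in L540 they were CFAP47 (4.21), CTSH (4.51), STYK1 (4.72) and TP53INP1 (4.72).

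By camera on the same contrast, 12 lists differed, 5 upward and 7 downward in L540 against Jurkat. With an estimated correlation 4 of them passed, with adjusted p of 0.00826 for heat shock, 0.043 for the unfolded protein response and 0.021 for both replication and mitosis, and the other 8 had 0.109 to 0.279. The median log2 difference was 1.08 for heat shock, 0.304 for the unfolded protein response, 0.31 for ATF4, 0.221 for AP-1 and immediate early genes and 0.165 for autophagy and lysosome. It was -0.817 for DNA replication, -0.74 for mitosis, -0.341 for the CHK1 and ATR checkpoint, -0.304 for metallothioneins, -0.273 for glycolysis and hypoxia, -0.194 for MYC targets and -0.18 for the respiratory chain. Of 100 drawn within-line splits of the arrays, the real one included, 8 gave as many probe sets as the real 3798 (highest other 6485) and 11 as many lists as the real 12 (highest other 13). Chance was not excluded, but this count had little power to exclude it, because a split that keeps control and treated L540 arrays apart carries the whole L540 effect. Of the other 99, 9 were such splits, of which 7 gave as many probe sets and 9 as many lists. The 90 that mixed them gave at most 57 probe sets, so the large probe set counts point to the structure of the L540 arrays. For lists this was less clear, as 1 of the 90 also gave 12.

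More probe sets passed in L540 (6470) than in Jurkat (201). With 10 possible splits of 6 arrays no share under 0.05 can be reached. The real split was the largest (1 of 10) for probe sets and for lists in each line, with the highest other at 0 probe sets in both lines and at 6 lists against 13 in Jurkat and 8 against 13 in L540. A wider spread between the Jurkat arrays is argued against, since the median residual SD was 0.1414 in Jurkat and 0.149 in L540. The L540 fold changes with the Jurkat residual spread gave 7335 probe sets, and the Jurkat fold changes with the L540 spread gave 227. The L540 count did not rest on a single array, as the lowest count with 1 array left out was 3586, without L540 control replicate 2. Whether an array was out of place cannot be told from this. Such an array would widen the spread in its group and tend to remove calls. A difference in sensitivity between the lines stays open and untested, with 1 line per disease and 1 dose.

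Nearly all Jurkat calls were increases, 94.5% of 201. Treated arrays brighter in their median are argued against, because the medians overlapped. On the log2 scale they were 5.38 to 5.4 in controls and 5.37 to 5.44 with ixazomib. Centring each array therefore had little to change, and the share was 93.7% after it. A threshold that only the largest changes pass may account for part of it: at an unadjusted p under 0.05 the share was 52.1% of 5206. About 2681 of these are expected by chance, which pulls the share toward an even one, and with that number subtracted as evenly split the share was 54.2%. No biological explanation was tested.

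CD68 rose in Jurkat by 1.71 on the log2 scale, and the innate immune receptor genes TLR6 and LY96, chosen after their values were seen, rose by 1.701 and 1.604. TLR6 and LY96 were left out by the filter on dim probe sets, which takes the mean over both lines, so the size of their rises may be uncertain. Myeloid cells among the treated cells would bring the other markers too. The other 11 myeloid markers had a median log2 fold change of 0.0583 (range -0.109 to 0.321), with S100A8 at 0.06 and LYZ at 0.08, far below 0.854, which is the CD68 value divided by 2. S100A8 and LYZ were also left out by that filter, so their low values carry little weight on their own. A regulation of CD68, TLR6 and LY96 within Jurkat cells stays open as a hypothesis, and it was not tested.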

How the results depend on the processing

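The tests on linear intensities and without the leading unplaced probe set IDs were chosen after the data were seen.

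No list, and no gene whose change is given here, changed sign under the alternatives run if past its threshold. In Jurkat, 201 probe sets passed (94.5% higher), 409 without dim probe sets (78% higher), 512 with an intensity trend and robust prior (74.6%), 480 with all 12 arrays in 1 fit (82.5%) and 494 on linear intensities (60.7%). With 1 array left out, 38 (without ixazomib replicate 3) to 52 (without control replicate 3) passed, with fewer arrays as part of the change. Centring, a second quantile normalization, array weights, only named probe sets (237, 73.4% higher) and omission of the leading IDs gave 175 to 258. In L540, 6470 passed, 4216 with only named probe sets, where fewer were tested, and 3586 (without control replicate 2) to 5656 (without ixazomib replicate 3) with 1 array left out, against 5848 to 8380 in the other settings, the block below aside. The difference between the lines gave 3798, and 2629 (without Jurkat control replicate 1) to 3345 (without L540 ixazomib replicate 3) with 1 array left out, and 2782 to 5183 in the other settings, again the block aside. The majority sign of the calls turned in some settings. In L540 it went from 3462 higher and 3008 lower to 2736 and 2920 without ixazomib replicate 3, and to 3671 and 3675 on linear intensities. In the difference it went from 1849 positive and 1949 negative to 2640 and 2543 without dim probe sets, 1594 and 1524 after centring, and 2506 and 2464 with the intensity trend. It also turned without Jurkat ixazomib replicate 2 (1658 and 1586) or 3 (1557 and 1552), and without L540 ixazomib replicate 2 (1647 and 1584). Apart from fewer arrays or probe sets, the cause was not tested.

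Of the lists, 13 passed in Jurkat, 13 in L540 and 12 in the difference. With an estimated correlation 2, 0 and 4 passed. With fry, a test of a different question, 13, 20 and 19 passed. With 1 array left out 12 to 13, 12 to 14 and 10 to 13 passed. The correlation between the lines, 0.304, was 0.363 without dim probe sets, 0.465 over genes called in at least 1 line, and 0.267 (without Jurkat ixazomib replicate 2; 0.27 without Jurkat control replicate 3) to 0.311 (without Jurkat ixazomib replicate 1) with 1 array left out. Other alternatives gave 0.303 to 0.305. The genes called in at least 1 line were selected by the same fold changes, which can raise the correlation by itself. The cause of the other shifts was not tested.

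Of 16 named genes past in Jurkat, 12 lost the call without at least 1 array, and 3 under an alternative of another kind, the block aside. Of 50 in L540, 6 and 3 did. Of 21 that had not passed in Jurkat, 5 did under another alternative (XBP1, MT2A, EXO1, NEK2 and CDC6). Of 55 differences between the lines that passed, 45 passed under every alternative run, 7 lost the call without 1 array, and 4 (ACAT2, CFAP47, JUND and TP53INP1) after centring. Of 23 that had not passed, 9 did under at least 1 alternative. Of the genes named after their values were seen, 10 passed in Jurkat, of which 8 lost the call without 1 array and 2 (VCP and PFN2) after centring. In L540 22 passed, of which 4 lost it without 1 array and 2 (EMP3 and WDR74) after centring. The array signal limits dim probe sets, which the filter above leaves out.

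With the replicate number as a replicate block, 7 probe sets passed in Jurkat, 3591 in L540 and 2066 in the difference, 13 of the 16 named genes past in Jurkat, 5 of the 50 in L540 and 6 of the 55 differences lost the call (the 6 being ACAT2, ASNS, DSCC1, JUND, NEK2 and PGAM1), of the genes named later 10 of 10 in Jurkat, 4 of 22 in L540 and 1 of 3 differences (NPLOC4) lost it, the lists numbered 13, 13 and 12, and the correlation was 0.304, unmoved by construction. Pairing by number was not established and is not excluded. Residuals of arrays with the same number correlated at 0.024, 0.089 and 0.069 in Jurkat and -0.07, 0.0093 and -0.037 in L540, all under the set threshold of 0.1. Jurkat control replicates 2 and 3 correlated best with their own number (highest other -0.00065 and 0.066). Jurkat control replicate 1 and the L540 controls did not.

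The planned test of L540 control against Jurkat control and its lists at baseline were not run in any setting, since the lines were taken as normalized separately.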

Other observations

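The hypotheses below came from genes seen in the data. The group of VCP-binding proteins was written down after 5 members had been seen, and the microRNA test was chosen after the microRNA changes were seen.

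VCP, the gene of the ATPase that extracts ubiquitin-tagged proteins for degradation, rose with 4 genes of its cofactors in both lines, chosen after their values were seen. In Jurkat the log2 fold changes were 0.53 ± 0.0727 (SE, 3 against 3 arrays) for VCP, 0.66 ± 0.076 for NPLOC4, 0.60 ± 0.0738 for UFD1, 0.74 ± 0.0786 for NSFL1C and 0.59 ± 0.0724 for PLAA, with limma adjusted p from 0.019 to 0.0498. All 5 Jurkat calls were lost without any 1 of the 6 arrays (adjusted p = 0.0701 to 0.243), and that of VCP after centring (0.0746). In L540 they were 0.62 ± 0.0709, 1.18 ± 0.0722, 1.16 ± 0.0913, 1.33 ± 0.0771 and 0.86 ± 0.0719. The difference between the lines passed for NPLOC4, UFD1 and NSFL1C (adjusted p = 0.00635, 0.0111 and 0.00474) and not for VCP or PLAA (0.691 and 0.108). PLAA passed under 3 alternatives, without dim probe sets, with the intensity trend and with only named probe sets.

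A hypothesis is that the wider group of VCP-binding proteins rises with ixazomib. It was tested on the 24 other measured members of 35 listed, against 10000 random lists matched on expression. In L540 their median was 0.293, at percentile 99.97 (95th percentile of random lists 0.109), with 11 higher and 2 lower, and 13 and 2 adjusted over the list alone. In Jurkat their median was 0.0045, at percentile 82.11 (95th percentile 0.028), with 0 past by limma and 2 higher adjusted over the list alone. The random genes were drawn singly, so the percentiles make no allowance for correlation between members of the group and may overstate a rise. With that limit the hypothesis may hold for L540, and in Jurkat the test went against a rise of the wider group.

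The probe set of MIR616, a microRNA that lies inside the gene DDIT3, rose in L540 by 3.06 ± 0.263 (adjusted p = 0.00108), beside 2.37 for DDIT3. A candidate explanation is that microRNA probe sets on this array read the transcript of the gene they lie in. Over the 98 other microRNAs inside a gene called in L540, Spearman's rho between their log2 fold changes and those of the gene was 0.337. The 95th percentile in 10000 shuffles of these pairs was 0.166. Over all pairs but MIR616 rho was 0.162, without shuffles of that larger set. Of the 98, 59 had the sign of their gene. Of the 10 of them that were called, 10 went the same way as their gene. Another 8 microRNAs were called inside a gene that was not, 6 with the sign of the gene and 2 with the opposite sign, such as MIR3198-1 at -1.10 inside BID at 0.01. Some changed genes held a microRNA with little change, such as UHRF1 at -1.72 with MIR4747 at 0.16 and DTL at -1.36 with MIR3122 at -0.02, pairs chosen after their values were seen. So the explanation may hold for part of these probe sets. A microRNA that itself changed together with its gene would give the same values, so the test cannot tell the 2 apart. Pairs are not independent where microRNAs share a gene, and the strand of each microRNA was not used.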
